A study of Drosophila melanogaster with 3 samples.

How the data were processed

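Chromatin from Drosophila melanogaster embryos of both sexes, collected at 0 to 14 hours of development, was sheared by sonication to 200 to 800 bp and immunoprecipitated with an antibody against GFP. The flies carried a transgene of erect wing (ewg) fused at its C-terminal end to eGFP, so that the antibody recovers DNA bound by the tagged Ewg protein. The labels describe 3 biological replicates in 1 group. The series holds no control sample of its own, and every comparison below is between replicates, or between peaks and other parts of the genome.

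The deposited data are peak lists on the dm6 and dm3 builds. For each build there is a permissive list per replicate and a permissive list from the 3 replicates pooled. There is also the authors' optimal set, which was thresholded by irreproducible discovery rate (IDR). The permissive lists are described in the authors' file records as peaks and background. The file records trace every list to alignments of the replicates and to a control alignment that all lists of a build share. The aligner, the peak caller and their settings are not given in the sources used here. The signal of each peak is the authors' value from the deposited narrowPeak files; its scale was not equalised between lists. The deposited q-value of each peak, as −log10, reaches a ceiling in each list and was used only to count regions at that ceiling. The summit is the deposited offset from the start of each interval. Read counts are not part of these lists, so the depth of the libraries is unknown, and no depth-based limits are given. Intervals at 95% are exact (Clopper-Pearson) for shares of peaks and cover the counting of peaks only.

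All coordinates, sequences and gene annotations are from dm6. Sequence came from the reference assembly of that build, and 13945 protein-coding genes on chromosomes X, 2L, 2R, 3L, 3R and 4 came from Ensembl release 115. The dm3 lists were used for counts, chromosome shares and, among themselves, the presence of peaks in the replicates, with no conversion of coordinates. Positions are counted from 1. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

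A peak of the optimal set was called present in a replicate when a summit lay within 100 bp among the 6793 strongest regions of that replicate's permissive list, 6793 being the size of the optimal set. The share expected by chance came from 100 circular shifts of the peaks along each chromosome. Relative signal is the signal of a peak in a replicate divided by that replicate's median over the 5852 peaks with a summit in the permissive lists of all 3 replicates, and is given as mean ± SD over the replicates. A promoter peak has its summit within 500 bp of any transcript start of a protein-coding gene, and a gene with such a peak is called bound. Non-coding genes were not used, so summits classed as intronic or intergenic may lie at starts of such genes. Genes that share a peak were each counted. Optimal peaks were compared with the 21973 regions of the pooled permissive list that overlap no optimal peak, by two-sided Fisher's exact test. The X share was tested by a two-sided exact binomial test.

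The palindrome searched for was GCGCAYGCGC, the core of the site of NRF-1, the vertebrate homologue of Ewg. It was sought on both strands within 100 bp of each summit and in a control window shifted by 1000 bp, alternately to either side, and the paired shares were compared by a two-sided exact McNemar test. Median log2 signal was compared by a two-sided permutation test with 100000 resamples. Core promoter motifs other than the initiator were sought from 200 bp upstream to 50 bp downstream of 1 start per gene, the outermost 5′ start. The initiator was sought only within 10 bp of that start. The TATA box and the initiator were sought on the strand of the gene alone, the other motifs on both strands. Bound here means an optimal summit within 500 bp of that start. Taking 1 start per gene there was decided after the files had been read and before the motif result was seen. Motifs and 20 gene lists were each tested by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 7 motifs or the 20 lists. Peaks and genes are not replicates, so these p-values describe these peak sets and not the variation between embryo collections. Of the list members, 7 genes of mitochondrial DNA upkeep and import and 6 in other lists matched no gene symbol of the annotation and were left out. Of these 13, 8 were found later under other symbols, 5 of them bound, and were added in an alternative chosen after seeing the data; the other 5 stay out.

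The motifs, lists, tests and most alternatives were fixed before the data were examined. Genes are named by a rule fixed at the same time. It takes ewg, the genes nearest to and within 500 bp of the 15 strongest optimal peaks, the up to 3 bound members with the highest signal in each list, and the 5 strongest optimal peaks over 1000 bp from any protein-coding start. A gene that the rule takes is not reported here. The alternatives were other overlap rules and promoter windows, no rank limit, the dm3 lists, the 3396 strongest peaks alone, and other motif windows, mismatches and shuffled controls. Others were a background of genes with a permissive region, counting only the nearest gene of each peak, and leaving out each replicate in turn. For the last, except for the difference in signal, which used the ranks in the other replicates, the optimal peaks present in both other replicates were kept, so the number of peaks fell as well. The optimal set was not called anew and still rests on all 3 replicates. Alternatives added after seeing the data were 1 start per gene for the lists and 1 summit per interval. Peaks present in all 3 replicates, the hexamer TGCGCA and the list members found under other symbols were also added then.

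The statistics were tested on simulated data. With a list of 85 genes bound at 60% against 25% of the 13945 genes, the list test made a call in 100% of 100 draws. It did so in 96.0% for a list of 36 genes and in 36.0% for a list of 12 genes, and it called unchanged lists in 0.375% of tests. Small lists that did not pass the threshold were therefore tested with little power. Smaller differences than 60% against 25% were not simulated, so the power for them is unknown at any list size. All of 665 exact palindromes planted in 6793 random windows were found, which checks only that the search runs.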

Results

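Binding of GFP-tagged Ewg, a transcription factor needed in the nervous system and in muscle and the fly homologue of NRF-1, was mapped by chromatin immunoprecipitation in whole embryos of 0 to 14 hours, in 3 biological replicates of 1 group. The authors' optimal set held 6793 peaks on dm6, with signal from 141.8 to 4999 and a median of 269.9. These were the 6793 strongest of the 30000 regions in the pooled list. On dm3 the optimal set held 6631 peaks. Read depth is unknown from these lists. The share of permissive regions at the highest −log10 q of their list was 9.66% in replicate 1, 32.3% in replicate 2 and 15.7% in replicate 3.

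The ewg gene itself held 1 of the 15 strongest optimal peaks. The gene lies on the minus strand of chromosome X from 268509 to 279718. Its strongest peak, from 275896 to 276791 with the summit at 276251, ranked 13 of 6793 and lay 126 bp from an internal transcript start at 276377. Its relative signal was 10.1 ± 2.07 (SD, n = 3), that is, about 10.1 times the median peak. A peak with its summit at 279540, 94 bp from the nearest start at the 5′ end of ewg, had a relative signal of 4.76 ± 0.71 (SD, n = 3). An intronic summit at 278193 had 3.94 ± 1.58 (SD, n = 3). A weaker summit at 282066 lay upstream of ewg in an intron of CG3777, with 1.28 ± 0.69 (SD, n = 3).

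**Figure D1:**
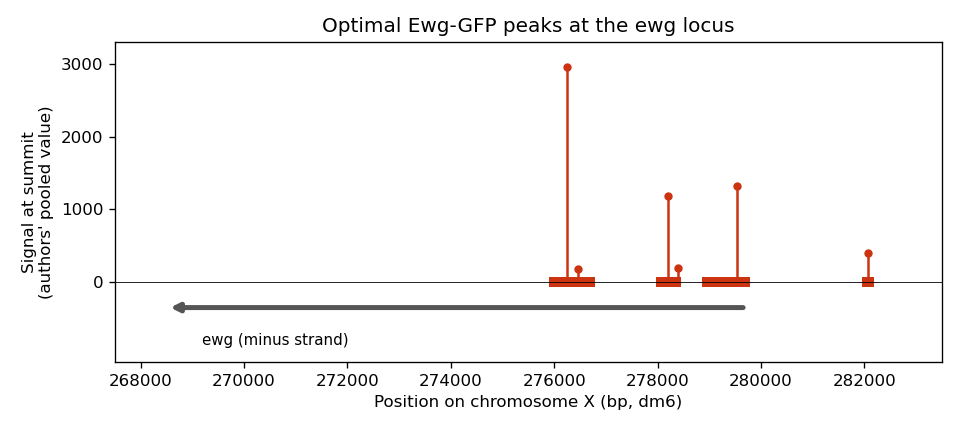
Optimal peaks at the ewg locus on chromosome X (dm6). The horizontal axis is position in bp, red bars are peak intervals, stems give the authors' pooled signal at each summit (no unit), and the grey arrow is the ewg gene in its direction of transcription. The highest stem, with a signal of 2966, stands at 276251.

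Most of the 15 strongest peaks lay at promoters. The first in rank, at CG31688 (2L, 20425779 to 20426348), had a relative signal of 16.9 ± 2.75 (SD, n = 3). The next was at Gpdh1, which encodes glycerol-3-phosphate dehydrogenase, with the summit 1 bp upstream of the start at 5943643 on 2L and a relative signal of 16.8 ± 1.89 (SD, n = 3). The peak at 14-3-3epsilon, an adaptor protein of kinase signalling, reached 13.4 ± 2.31 (SD, n = 3) and held the palindrome. The other genes named by rank were gprs, CG14100, px, CG5065, Rtnl1 (a reticulon of the endoplasmic reticulum), CG3955, stj (a calcium channel subunit) and Ugalt (a nucleotide sugar transporter). Their relative signals ran from 10 ± 1.75 at CG3955 to 12.6 ± 2.72 at CG14100 (SD, n = 3 each). The difference between these extremes was smaller than the SD at CG14100.

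Strong peaks away from protein-coding promoters were also present. The strongest among the peaks over 1000 bp from any protein-coding start lay in an intron of ush at 481057 on 2L, at −1369 bp from the start of cbt, which encodes a zinc-finger transcription factor, with a relative signal of 10.8 ± 1.36 (SD, n = 3). An intronic peak of CG11050 (summit 6612735 on 2L) had 10.6 ± 1.26 (SD, n = 3). An intergenic peak at 13035336 on 2R, 11920 bp from the start of CG13323, had 10.4 ± 1.26 (SD, n = 3). Another at 6904224 on 3L lay 9740 bp from the start of Prat2, a gene of purine synthesis, with 8.41 ± 2.01 (SD, n = 3). An intronic peak of Trl, the gene of the GAGA factor, had 7.92 ± 0.83 (SD, n = 3) at 14759518 on 3L.

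The first comparison asked whether the replicates bound the same places. Replicate 1 held 82.92% of the optimal peaks, replicate 2 held 83.51% and replicate 3 held 82.11%, a mean of 82.85% ± 0.70 (SD, n = 3). These peaks passed the authors' IDR threshold and were the strongest of the list pooled from the same replicates. These shares therefore do not measure agreement independently. Without that selection, of the 6793 strongest regions of a replicate, 70.71% had a summit within 100 bp among those of the other for replicates 1 and 2, 75.61% for 1 and 3, and 69.75% for 2 and 3. Of the 6793 peaks, 4216 (62.06%) were present in all 3 replicates, 1713 in exactly 2, 810 in 1 and 54 in none. Shifted peaks were present in all 3 in 0.522% on average and in at most 0.692%. Presence fell with signal, from 99.41% of the strongest 679 peaks to 1.32% of the weakest 682, where the rank limit leaves little room. With no rank limit, 86.15% were present in all 3. With a reciprocal overlap of 50% in place of the summit distance the share was 43.78%. Across the 5852 peaks measured in each replicate, which are not independent replicates, log2 signal had a Pearson correlation of 0.865 between replicates 1 and 3, 0.749 between 1 and 2, and 0.742 between 2 and 3. The Spearman correlations were 0.847, 0.709 and 0.703 in the same order.

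**Figure D2:**
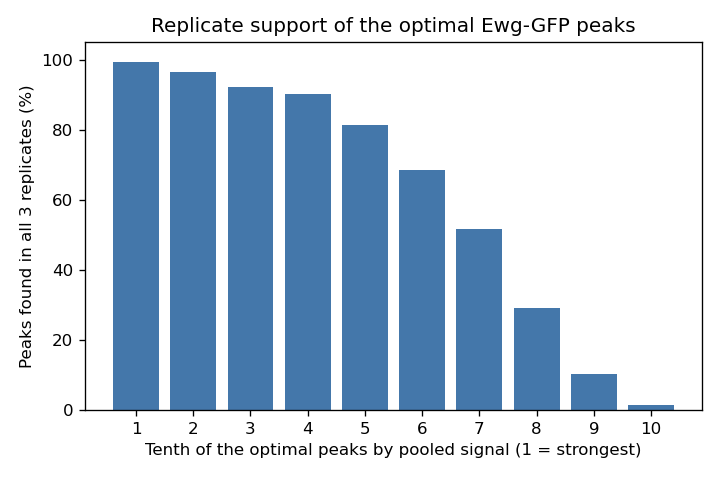
Share of the optimal peaks present in all 3 replicates (vertical axis, percent) for 10 classes of peaks by pooled signal (horizontal axis, 1 the strongest). Each bar is 1 class of 679 to 682 peaks. The share falls from 99.41% to 1.32%.

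The second comparison asked where in genes the protein bound. Promoters held 3277 optimal peaks, 48.24% of the total (95% interval 47.05 to 49.44). They held 17.53% of the permissive-only regions and made up 11.45% of the genome. The odds ratio against the permissive-only regions was 4.384 (95% interval 4.132 to 4.653, two-sided Fisher's exact test). The strongest 6793 regions of each replicate gave 47.76% ± 3.17 (SD, n = 3), far above the 17.53% of the permissive-only regions. That background is 1 value from the pooled list, so its own spread between replicates was not measured. Of the other optimal peaks, introns held 31.84% of the total and intergenic sequence 17.39%. Coding exons held 0.942%, 5′ UTRs 0.824% and 3′ UTRs 0.766%. Promoter peaks had a median signal of 300.9 and other peaks 245.3.

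The share of peaks on the X chromosome was close to its share of the bases, and that of chromosome 4 was below it. The X chromosome held 17.96% of the peaks (95% interval 17.05 to 18.89) and 17.58% of the assembled bases (p = 0.416, two-sided exact binomial test). It held 18.6% of the permissive-only regions (p = 0.238, two-sided Fisher's exact test), and on dm3 18.01% of the peaks and 18.99% of the permissive-only regions (p = 0.0771, two-sided Fisher's exact test). Chromosome 4, small and mostly heterochromatic, held 25 peaks, or 0.368% against 1.007% of the bases (p = 2.77e-09, two-sided exact binomial test). The permissive-only regions had 0.2412% there (p = 0.0832, two-sided Fisher's exact test against the optimal peaks). Of the other arms, 2L held 18.58% against 17.56% (exact binomial p = 0.0289, not adjusted for the 6 chromosomes). PlexA, a semaphorin receptor of axon guidance, was among the bound genes of chromosome 4, with a relative signal of 2.42 ± 0.883 (SD, n = 3).

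The palindrome of the NRF-1 site was concentrated at summits, but its exact form was present in few peaks. With at most 1 mismatch, 10.5% of summits and 1.71% of shifted windows held it, a ratio of 6.15. The values that follow are for exact matches. Within 100 bp of the summit, 132 optimal peaks (1.94%, 95% interval 1.63 to 2.3) held GCGCAYGCGC, against 8 (0.118%) of the shifted windows, a ratio of 16.5 (p = 4.56e-30, two-sided exact McNemar test). The size of this ratio is uncertain, since it rests on 8 control windows: it was 50, 18.6 and 25.8 among the peaks present in both other replicates when replicates 1, 2 and 3 were left out, and 56 and 7.29 with windows of 50 and 250 bp on either side. The strongest 6793 regions of each replicate gave 1.82% ± 0.204 (SD, n = 3). The permissive-only regions had 0.765%. Among promoter peaks 1.31% held the palindrome, and among other peaks 2.53%. The genome has 522 such sites on these chromosomes, and 135 of them (25.86%) lay within 100 bp of an optimal summit. Of the sites in promoters 35.2% were at optimal summits, and of the others 22.92% (odds ratio 1.824, p = 0.00968, two-sided Fisher's exact test). Con, a cell adhesion gene of axon pathfinding, had a palindrome in its promoter peak at 4976409 on 3L.

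**Figure D3:**
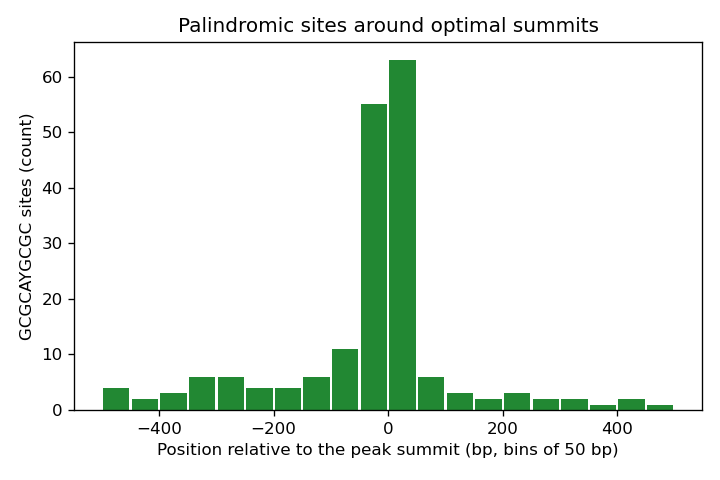
Number of GCGCAYGCGC sites on either strand (vertical axis, count) by distance from the optimal summits (horizontal axis, bins of 50 bp). The bins on either side of the summit hold 55 and 63 sites.

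Peaks with the palindrome had a median signal of 290.9 and those without it 269.8, a difference of 0.11 on the log2 scale that did not pass the threshold (p = 0.308, two-sided permutation test). Among promoter peaks alone the difference was 0.485 (permutation p = 0.0147). With the mean rank in replicates 1 and 3 in place of the signal, the log2 difference had the opposite sign, −0.255 (permutation p = 0.072).

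Bound and unbound promoters differed in the share that carried each of the 7 core promoter motifs. The DRE, bound by the factor DREF, was in 12.55% of 3307 bound and 7.483% of 10638 unbound promoters (odds ratio 1.774, exact adjusted p = 1.403e-17). The M1BP motif was in 7.892% against 4.334% (odds ratio 1.892, exact adjusted p = 3.149e-14) and the GAGA motif in 7.681% against 4.493% (odds ratio 1.768, exact adjusted p = 1.09e-11). The TATA box was rarer in bound promoters, 5.443% against 11.32% (odds ratio 0.4511, exact adjusted p = 1.225e-24), and so was the initiator, 7.711% against 9.804% (odds ratio 0.7686, exact adjusted p = 0.000285). The E-box had an odds ratio of 1.426 (exact adjusted p = 0.0005035) and the palindrome one of 3.836 (exact adjusted p = 0.0001286). All are two-sided Fisher's exact tests adjusted over the 7 motifs. When only promoters with a permissive region served as background, 2 of the 7 passed, the TATA box (odds ratio 0.7148) and the initiator (0.7178). The other odds ratios shrank to 1.188 for the DRE, 1.092 for M1BP, 1.188 for GAGA, 1.189 for the E-box and 1.829 for the palindrome.

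The gene lists asked which groups of genes were bound. Of the 13945 protein-coding genes, 3679 (26.38%) had an optimal peak at a promoter. By two-sided Fisher's exact test adjusted over the 20 lists, 8 lists were bound more often than other genes and 2 less often. Cytosolic ribosomal protein genes were bound in 61 of 85 cases (71.76%, odds ratio 7.194, 95% interval 4.412 to 12.08, exact adjusted p = 5.081e-17). Among them RpL7 had a relative signal of 4.94 ± 0.357 and RpS27 of 4.08 ± 1.14 (SD, n = 3 each). Neuronal and synaptic genes were bound in 26 of 36 cases (72.22%, odds ratio 7.298, 95% interval 3.401 to 16.98, exact adjusted p = 5.855e-08). Their strongest promoter peaks were at cpx, the complexin of synaptic vesicle release (5.22 ± 1.83), at the presynaptic calcium channel gene cac (4.33 ± 1.63) and at the neuroligin gene Nlg3 (4.28 ± 1.23, SD, n = 3 each).

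Odorant and gustatory receptor genes, which act in sensory neurons, had 0 of 119 members bound (upper 95% bound of the odds ratio 0.0869, exact adjusted p = 1.653e-15). Cuticle protein genes had 2 of 119 (odds ratio 0.04719, exact adjusted p = 1.28e-12). The bound members were Cpr31A and Cpr, and Cpr encodes a cytochrome P450 reductase that the name pattern of the list had caught. These calls and the calls of the cytosolic ribosomal and the neuronal list passed under every alternative tried, though their odds ratios moved. Against genes with a permissive region the odds ratio was 3.373 for the neuronal list (exact adjusted p = 0.0197), 3.415 for the cytosolic ribosomal list (exact adjusted p = 8.96e-05) and 0.1187 for the cuticle list (exact adjusted p = 0.00633). With 1 start per gene, an alternative chosen after seeing the data, that of the neuronal list was 3.61 (exact adjusted p = 0.000697).

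The other 6 lists bound more often than other genes lost their calls under some alternatives. When only the 6529 genes with a permissive region at a promoter served as background, none of these 6 passed (odds ratios 1.281 to 1.844), so their members were not shown to be bound more often than other genes with such a region. Axon guidance genes were bound in 16 of 30 cases (odds ratio 3.198, exact adjusted p = 0.004039), with Sema2a at 3.74 ± 1.29 and Con at 2.43 ± 0.989 (SD, n = 3 each). Segmentation, homeotic and dorsoventral patterning genes were bound in 19 of 36 cases (odds ratio 3.129, exact adjusted p = 0.002953), with the strongest peaks at en (6.52 ± 1.31), opa (4.0 ± 1.2) and Dfd (3.21 ± 1.27, SD, n = 3 each). Wnt/Wingless pathway genes were bound in 15 of 32 (odds ratio 2.468, exact adjusted p = 0.02842), with the kinase genes gish at 4.68 ± 0.966 and sgg at 4.45 ± 0.29 and with ebd1 at 4.14 ± 1.18 (SD, n = 3 each). Genes of DNA replication and the cell cycle were bound in 18 of 39 (odds ratio 2.398, exact adjusted p = 0.02113), among them E2f2 (3.32 ± 0.184), Dp (2.26 ± 0.335) and RnrS (1.89 ± 0.377, SD, n = 3 each). The optimal peaks were called from the 3 replicates together. To leave a replicate out, only those present in both other replicates were kept (4706, 4908 and 4747 peaks without replicates 1, 2 and 3). The replicate and a filter against weak peaks thus change together. The call of this list was lost in each of these sets (odds ratios 1.229, 1.566 and 1.53, exact adjusted p = 0.685, 0.379 and 0.312). In the set without replicate 2, where 2800 genes were bound and 5 of the 10 calls were left, the patterning list had an odds ratio of 1.754 (exact adjusted p = 0.283) and the Wnt/Wingless list one of 2.089 (exact adjusted p = 0.182). With 1 start per gene, chosen after seeing the data, the Wnt/Wingless list also lost its call (odds ratio 1.687, exact adjusted p = 0.292).

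Of the 3 mitochondrial lists, 2 passed. Mitochondrial ribosomal protein genes were bound in 33 of 73 cases (odds ratio 2.314, exact adjusted p = 0.001928), with mRpL41 at 8.44 ± 1.66, mRpS10 at 8.29 ± 2.09 and mRpS23 at 6.85 ± 1.12 (SD, n = 3 each). The summit at mRpS23 lay 390 bp from its start. Genes that share a peak were each counted, so such signals can belong to a neighbouring gene as well. When only the gene nearest to each peak counted, the odds ratio turned to 0.6342 (exact adjusted p = 0.319), and in the set without replicate 2 it was 1.723 (exact adjusted p = 0.127). Respiratory chain and ATP synthase genes were bound in 31 of 70 (odds ratio 2.228, exact adjusted p = 0.004039), with ND-B15 at 3.61 ± 1.96, ND-MWFE at 2.39 ± 0.768 and ND-51 at 2.31 ± 0.104 (SD, n = 3 each). This call was lost in each of the smaller sets without replicate 1, 2 or 3 (odds ratios 1.42, 1.278 and 1.153, exact adjusted p = 0.347, 0.494 and 0.771), and also in the 3396 strongest peaks (odds ratio 1.215, exact adjusted p = 0.602), so the loss is not put down to any replicate. Genes of mitochondrial DNA upkeep, transcription, translation and import were bound in 7 of 30 (odds ratio 0.849, exact adjusted p = 0.8371), among them mEFTs (3.92 ± 0.933) and mTerf5 (1.7 ± 0.202, SD, n = 3 each), and mtTFB1 with a pooled signal of 449.7.

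The remaining lists did not pass the threshold in the main analysis, and 3 of them passed under an alternative. With a promoter window of 250 bp the initiation factors (odds ratio 2.05) and the glial genes (3.583) passed (exact adjusted p = 0.049 each). When only the gene nearest to each peak counted, the glial genes passed (odds ratio 4.01, exact adjusted p = 0.0429) and the proteasome genes were bound less often (odds ratio 0.2661, exact adjusted p = 0.0425). In the main analysis, translation initiation factors had 17 of 44 bound (exact adjusted p = 0.1447), with eIF6 at 5.47 ± 1.23, eIF4G2 at 4.83 ± 0.0988 and eIF4EHP at 4.36 ± 1.14 (SD, n = 3 each). Glial genes had 6 of 12 (exact adjusted p = 0.1447), with loco at 4.89 ± 0.782 and moody at 2.92 ± 0.239 (SD, n = 3 each). Splicing factors had 12 of 32 (exact adjusted p = 0.2307), SF2 at 2.3 ± 0.289 and U2af50 at 2.18 ± 0.559 among them (SD, n = 3 each). Heat shock genes had 7 of 17 (exact adjusted p = 0.2313), with Hsp27 at 4.74 ± 0.834, Hsp26 at 3.02 ± 0.752 and Hsp83 at 2.4 ± 0.267 (SD, n = 3 each). Germline genes had 6 of 14 (exact adjusted p = 0.275), with bgcn at 2.82 ± 0.293, gcl at 1.96 ± 0.35 and orb at 1.58 ± 0.185 (SD, n = 3 each). The germline and splicing counts leave out 1 bound gene each, nanos and SNRPG, which the annotation holds under symbols other than those of the lists; with them the counts are 7 of 15 and 13 of 33, and neither list passes (exact adjusted p = 0.134 and 0.149, an alternative chosen after seeing the data).

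Proteasome genes had 9 of 48 bound (exact adjusted p = 0.3002), Rpn2 at 1.51 ± 0.364 and Rpn5 at 1.39 ± 0.584 among them (SD, n = 3 each). Muscle genes had 7 of 30 (exact adjusted p = 0.8371), with Msp300 at 2.52 ± 0.479, tin at 2.42 ± 0.0644 and Mef2 at 2.21 ± 0.755 (SD, n = 3 each). Hemocyte and fat body genes had 2 of 15 (exact adjusted p = 0.4233), the transcription factor genes gcm and ush, each at 1.69 with SDs of 1.02 and 0.768 (n = 3). Chorion and vitelline membrane genes had 1 of 16 (exact adjusted p = 0.1447). That gene was Cp190, which encodes an insulator protein and not an eggshell protein (3.69 ± 0.721, SD, n = 3).

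**Figure D4:**
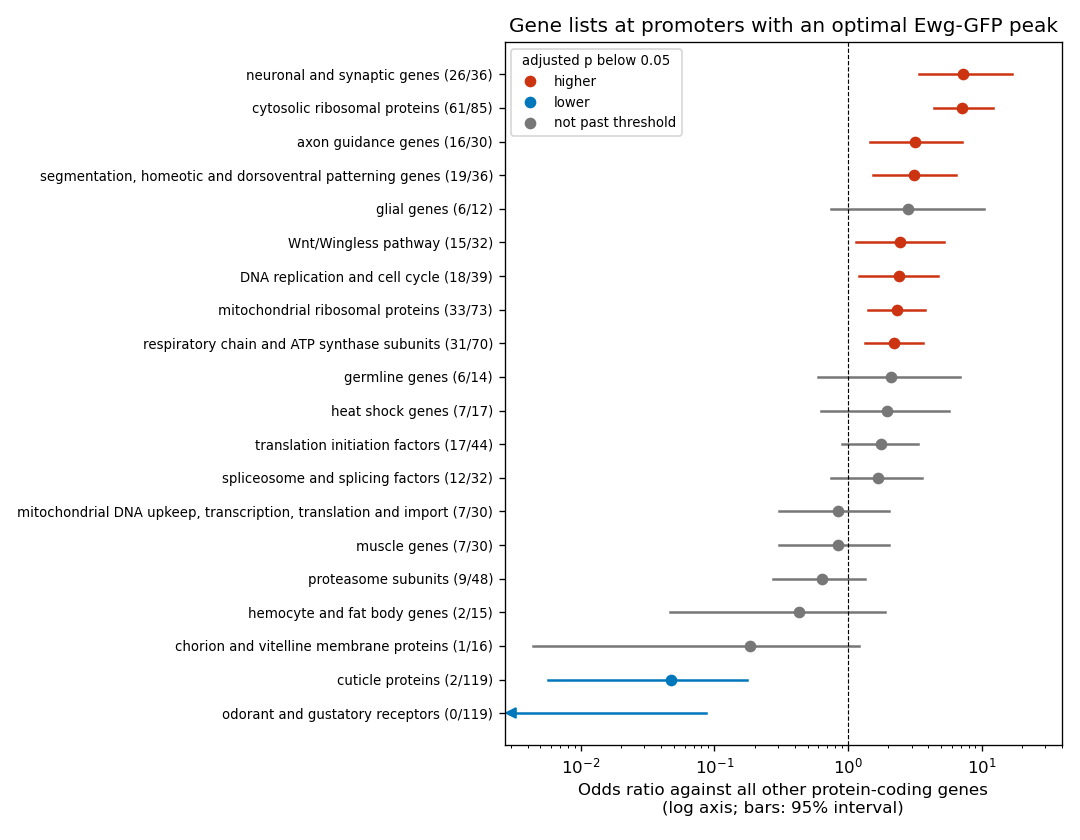
Odds ratio of being bound for each of the 20 gene lists against all other protein-coding genes (horizontal log axis, points with 95% intervals, the arrow an estimate of 0), with bound and total members in brackets. Red lists were bound more often and blue lists less often at an adjusted p below 0.05, and grey lists did not pass. The neuronal and the cytosolic ribosomal lists have the highest odds ratios, 7.298 and 7.194.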

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

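In the dm3 lists, which the comparisons used only for counts, shares and presence in replicates, 6 optimal peaks lay on heterochromatin scaffolds outside the main chromosome arms. They were flagged because they lay outside the chromosomes used for the promoter, motif and gene comparisons and were more than a set limit of 3. The dm3 share of peaks present in the replicates did include them. There were 3 on 2RHet, with a highest signal of 367.8 at rank 2236, 2 on 2LHet and 1 on 3RHet. The dm6 optimal set had none outside the chromosomes X, 2L, 2R, 3L, 3R and 4. Coordinates were not converted, so whether dm6 places this sequence within those chromosomes was not tested. With 1 group of 3 replicates, no sample was tested for its distance from the others, and there was no difference between groups to test.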

How the results depend on the processing

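The alternatives gave 283 values, of which 217 counted as kept. Most values were kept when they held their direction and side of the threshold, so lists that passed in neither setting count too. Shares of peaks present in all replicates were kept when they moved by less than 0.70, the SD of the shares present in each single replicate. Counts of calls were kept when they stayed within a set factor of the main count. Of the rest, 32 fell short of the threshold, 5 newly passed it, 11 moved and 18 changed direction. Alternatives with 1 start per gene, 1 summit per interval, peaks present in all 3 replicates, the hexamer TGCGCA and list members found under other symbols were chosen after seeing the data. The promoter share and the palindrome share were higher than their controls under each alternative. The share of peaks present in all replicates was 70.12% with an overlap of at least 1 bp, 43.78% with a reciprocal overlap of 50% and 86.15% with no rank limit. Leaving out each replicate, which asks for presence in 2 rather than 3, gave 69.28% to 72.25%. The X share fell below its reference in the 3396 strongest peaks (16.99%, exact binomial p = 0.379) and among promoter peaks (16.54% against 17.01% of starts, exact binomial p = 0.486), without passing the threshold. The log2 difference between peaks with and without the palindrome was 0.485 among promoter peaks, and the ranks gave −0.255 to 0.150 when each replicate was left out, the lowest without replicate 2. The cause was not tested.

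Of the core promoter motifs, 2 passed against promoters with a permissive region; the other odds ratios shrank to between 1.092 and 1.829. Of the gene lists, 4 passed against genes with such a region, 5 with the 3396 strongest peaks, 4 with peaks present in all 3 replicates, and 5 to 8 when each replicate was left out. With a window of 250 bp 12 passed, the initiation factor (odds ratio 2.05) and glial (3.583) lists being new. With the nearest gene of each peak 11 passed, the glial (4.01) and proteasome (0.2661, bound less often) lists being new and the mitochondrial ribosomal list lost. Where 4 passed, they were the cytosolic ribosomal, neuronal, receptor and cuticle lists. Of the counts with a replicate left out, the lowest, 5, was without replicate 2; these sets keep only peaks present in both other replicates, so the replicate and the filter were not separated. With 1 start per gene 9 passed, the Wnt/Wingless list being lost. With list members found under other symbols 10 passed, the same as in the report. Some odds ratios changed sides of 1, and the cause was not tested. That of the mitochondrial ribosomal list was 0.6342 with the nearest gene of each peak. Those of the mitochondrial DNA list were 1.089 with a window of 250 bp, 1.064 in the strongest peaks and 0.7957 to 1.184 when replicates were left out. Those of the muscle list were 1.0 with a window of 1000 bp, 1.219 with the nearest gene, 1.085 against genes with a permissive region, 1.331 in the strongest peaks, 1.129 with peaks in all 3 replicates and 0.9723 to 1.024 when replicates were left out. Those of the splicing list were 0.9237 with the nearest gene, 0.8356 with peaks in all 3 replicates and 0.8974 to 1.328 when replicates were left out. With the depth unknown, a peak missing from a replicate cannot be set apart from too few reads. No paired analysis was possible because the series has 1 group.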

Other observations

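The tests on the hexamer TGCGCA, on the ribosomal genes, on the ewg locus and on the glycolytic genes were chosen after the results that prompted them had been seen; the test on divergent promoters was set down before its result was seen.

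Genes that share a divergent promoter were bound more often. Of 4648 genes whose outermost start faces that of a neighbour within 1000 bp, 39.6% were bound there, against 15.8% of other genes (odds ratio 3.51, 95% interval 3.23 to 3.81, p = 2.93e-205, two-sided Fisher's exact test). The direction was the one predicted by the hypothesis that divergent promoters may be favoured, but this test cannot decide it. A pair of starts also gives each summit more chances to fall near a gene, which was not separated. Paired genes can share a summit, and each was then counted as bound. The p-value and the interval treat such genes as independent. Among promoters with a permissive region the odds ratio was 2.3 (95% interval 2.08 to 2.56), and the same limits apply.

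Some glycolytic and related genes stood near the top of the ranking. Of 14 such genes, listed after several had been seen there, 8 were bound (57.1% against 26.4% of other genes, odds ratio 3.73, 95% interval 1.13 to 13, p = 0.0144, two-sided Fisher's exact test). Since the list was drawn up from the ranking, this p overstates the evidence, and the hypothesis that the group is bound as such may not hold in other data. Gpdh1, Eno (enolase, relative signal 9.35 ± 0.746, SD, n = 3) and Pglym78 (phosphoglycerate mutase, 9.2 ± 1.29, SD, n = 3) ranked 2, 22 and 24. The other bound members, Gapdh2, Ldh, Hex-A, Pgk and Ald1, ranked 253, 704, 799, 1361 and 4303. Hex-C, Pgi, Pfk, Tpi, Gapdh1 and PyK were not bound.

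The hexamer TGCGCA, the end of the NRF-1 site, was in a larger share of summits than the full palindrome. A shorter pattern is also more common elsewhere, here in 4.73% against 0.118% of the shifted windows. Relative to those windows the palindrome was the more concentrated, with a ratio of 16.5 against 3.64. The hexamer came out first in a scan of all 2080 hexamers, run alongside a scan of all octamers, so it was picked as the best of many. It lay within 100 bp of 1168 of the 6793 optimal summits and in 321 (4.73%) of the shifted windows, a ratio of 3.64 (bootstrap 95% interval 3.25 to 4.09), and in 29.3% of the strongest 679 peaks. Base composition as the whole cause was argued against: the 95% interval of its share was 16.3% to 18.1% in the summit windows and 6.65% to 7.9% in the same windows with their dinucleotides shuffled (share 7.26%), though the shuffled share is itself above the 4.73% of the shifted windows. Promoter sequence in general was argued against too, since the hexamer was in 17% of optimal and 7.66% of permissive-only promoter regions (odds ratio 2.46, 95% interval 2.12 to 2.87). A candidate explanation is binding to single or degenerate sites, and no biological explanation was tested.

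The cytosolic ribosomal promoters were bound in most cases, and 2 technical explanations were weighed. Peaks that belong to neighbouring genes were argued against, because the odds ratio was 8.298 when only the nearest gene of each peak counted. Signal without the site, as very active promoters can give in such experiments, stays open: 8 of 61 peaks (13.1%) held TGCGCA against 17.4% at other bound promoters, with an odds ratio of 0.717 and an interval of 0.292 to 1.53 that allows either side of 1. The low count of sites and the lack of an untagged control sample in the series keep it open. No biological explanation was tested.

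Extra copies of the tagged ewg locus in the transgenic line would raise the whole gene alike. They were weighed as the whole cause of the strongest peak at ewg. This peak had 4.34 times the signal of the other summits of the gene measured in all 3 replicates (geometric mean, 95% interval 2.76 to 6.81, n = 3). The relative signals of those others ran from 0.69 to 4.76. This fold cannot decide the question. The strongest summit was picked for it, and a like rise of all summits leaves it unchanged. In the 7387 bp of the gene beyond its optimal peaks, from 268509 to 275895, the pooled list and those of replicates 1 and 3 had 0 regions, and the 4 in replicate 2 had a signal of at most 19.08 against 1538 at the peak. Called regions were thus not spread alike over the gene. This cannot decide the question either, because an even rise need not be called as a region. Whether extra copies add to the signal of all peaks of the gene was not tested, nor was a biological explanation. None of the 6 optimal summits at ewg had TGCGCA within 100 bp.

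Lists differed in signal between replicates, given here as values only. The median log2 relative signal of the peaks at bound neuronal genes was 0.685 in replicate 1, 1.44 in replicate 2 and 0.738 in replicate 3. For cytosolic ribosomal genes it was 0.802, 0.517 and 0.615. Chromosome 4 had 80, 267 and 63 permissive regions in replicates 1, 2 and 3.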
